A study of Mus musculus with 2 samples.

How the data were processed

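Both libraries were 10x Genomics Chromium single-cell RNA-seq of the 3' ends of polyadenylated RNA from mouse embryonic stem cells, and each held a pool of cells. Per the labels, the first pool, called the Zbtb11-labelled mix here, joined Zbtb11 knockout cells carrying a doxycycline-inducible tagged Zbtb11 transgene to wild-type cells carrying a histone H2B-GFP fusion. The second pool, the Zfp131-labelled mix, joined Zfp131 knockout cells with an inducible Zfp131 transgene to H2B-GFP wild-type cells. Knockout and wild-type cells were mixed at 9 to 1 in both, after 3 days without the 2 kinase inhibitors but with LIF and without doxycycline, so the rescue transgenes were not induced, and whether they leaked was not tested, and 10000 cells were aimed at. The titles, sample descriptions and source names of the second library name the Zfp131 knockout, whereas its genotype field names a Zbtb11 knockout carrying the Zfp131 transgene. The titles were followed, and the mixes are called by their labels for that reason.

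The deposited matrices hold UMI counts per gene and barcode, with no normalization. The values were whole numbers with different totals per barcode. Cell Ranger 4.0.0, Seurat 3.0 and the mouse genome build mm10 were used per the submitters' processing notes, and the role of each is not given in the sources used here. The matrices are named as filtered, and the rule of that filter is not given in the sources used here. Both matrices list the same 50687 features, of which 27882 and 27494 had a UMI in the Zbtb11-labelled and Zfp131-labelled mix. Gene positions came from GENCODE M21, in which 50376 feature identifiers were found.

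The features include the H2B-GFP transgene, which was meant to mark the wild-type cells. It had 0 of 77043247 UMIs in the Zbtb11-labelled mix and 0 of 75260446 in the Zfp131-labelled mix, which allows up to 0.0389 and 0.0399 CPM, the count scaled to a total of 1000000 UMIs. That limit holds only if the part of the transcript that 3' tags read is in the listed sequence, which is not given in the sources used here. The planned comparisons of unmarked with GFP-marked cells, and of GFP-marked cells between the mixes, could therefore not be made, and no cell carries a genotype. A comparison of clusters was added in their place after the data were examined.

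Cells with at least 1000 genes, under 10% mitochondrial UMIs and no doublet call were kept. Of 7510 and 6982 barcodes in the Zbtb11-labelled and Zfp131-labelled mix, 1 and 0 had fewer genes and 339 and 61 were at or above the mitochondrial limit. Scrublet in scanpy 1.11.5, run per library at an expected rate of 0.06, called 7 barcodes (0.0932%) and 12 barcodes (0.172%). Calls on under 0.5% of a library of this size mean that the caller did not work, so doublets remain among the 7164 and 6909 cells kept. An alternative without the 6% of barcodes with the highest doublet scores was added for that reason.

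UMIs of a gene were summed over the kept cells of a mix and divided by the mix's kept UMIs, 75676839 and 74795223, to give CPM, and likewise for groups of cells. With 1 library per mix there is no replicate, no test was made and no p-value is given. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and computed with scipy 1.17.1. These intervals cover counting error only, not the spread between cultures, clones or libraries. A gene passed the size rule when its log2 ratio was at least 1 in size with at least 10 CPM in the higher arm. The words higher, lower, rose and fell are kept for genes past that rule. A level of 0 took a floor of 3 UMIs and the ratio is then a bound. On counts simulated from the real means, with the changed genes drawn from those with at least 20 CPM, the rule called 100 of 100 genes changed 4-fold and 0 of 100 genes changed 1.5-fold. It called 0 of 7453 unchanged genes at the depths of the mixes and 0 of 7514 at depths like those of the remaining cells and the shared cluster. The simulated counts varied by counting error only. They therefore do not show how often the rule calls genes that differ between libraries, clones or cultures for other reasons.

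Gene lists were fixed before the data were examined: naive, core, and formative and primed pluripotency; primitive streak and mesoderm, definitive endoderm, primitive endoderm, neuroectoderm, neuron, trophoblast, 2-cell-like state, germ line, fibroblast, and endothelium and blood; Hox genes; targets of ERK, Wnt, LIF and STAT3, BMP, and p53; the Nodal pathway; Pol II pausing and elongation; the integrated stress response; immediate early and dissociation genes; nuclear OXPHOS subunits, mitochondrially encoded genes, mitochondrial ribosome and cytosolic ribosomal proteins; glycolysis and hypoxia; cholesterol synthesis; S phase; G2 and M phase; interferon response; and imprinted genes. Each of these 33 lists was described by its members with at least 10 UMIs over both arms. Members under 10 CPM in both arms could not pass the size rule and are counted among those that did not pass. The median log2 ratio was placed among 10000 random lists of the same size, matched on expression in 20 bins, as a percentile. Percentiles of at most 2.5 or at least 97.5 are called low or high. They describe these libraries and, since list members are not independent, are no test.

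Genes named in the text followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest log2 ratios among genes past the size rule with at least 20 CPM, leaving out predicted gene models, mitochondrially encoded and ribosomal protein genes, and up to 4 members of each list past the rule. Zbtb11, Zfp131, Pou5f1, Sox2, Nanog, Zfp42, Klf4 and Esrrb were always included. Genes that passed in 1 mix and stayed within 0.5 of 0 on the log2 scale in the other, the Y-linked genes, and the few genes that went opposite ways were chosen after their values were seen. Values of some single genes are not reported here.

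All kept cells were clustered together without batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was divided by leidenalg 0.10.2 at resolution 0.5. Clusters are numbered by size. A cluster was called by a cell type's name with the ending -like from marker lists fixed before the data were examined, when at least 3 markers exceeded the other cells at least 2-fold with at least 5 CPM and no other class led its top 10 genes, with these thresholds set after the data were examined. Class shares are also given from a clustering without any listed gene. The cluster with a large share of both mixes is called the shared cluster and all other kept cells the remaining cells.

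For remaining cells against the shared cluster, the genes were split at random into 2 sets. Cells were clustered on each set, and the ratios of the genes of one set were taken between cells grouped by the other set, so that no gene helped to define the groups it was compared in. The shared cluster from each set overlapped the shared cluster from all genes with Jaccard indices of 95.8% to 97.8%. Shares of cells with a UMI were taken after thinning each cell to 5000 UMIs, which left out 986 and 644 shallower cells.

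Alternatives chosen before the data were examined were no cell filter, a stricter filter of 2000 genes and 5% mitochondrial UMIs, doublet calls kept, TMM scaling (edgeR 4.0.16), equal weight for every cell, other minimum levels, other thinning depths, and other clustering settings. The 2 alternatives with another minimum of GFP UMIs could not be run. Alternatives added later were the clusterings without listed or Y-linked genes, the removal of the highest doublet scores, thinned cells, and leaving out differentiated or low-depth clusters. Calculations used Python 3.11.15, numpy 2.4.6 and scikit-learn 1.9.0, and plots matplotlib 3.10.9.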

Results

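The data are single-cell RNA counts from 2 libraries of mouse embryonic stem cells, 1 per knockout. The Zbtb11-labelled mix gave 7510 barcodes with 77043247 UMIs and the Zfp131-labelled mix 6982 barcodes with 75260446 UMIs. After filtering, 7164 and 6909 cells remained, with medians of 10082.5 and 10373 UMIs and 2986.5 and 3347 genes per cell. Mitochondrial UMIs reached 10% in 4.51% of barcodes (exact binomial 95% interval 4.06 to 5.01) of the Zbtb11-labelled mix and in 0.874% (0.669 to 1.12) of the Zfp131-labelled mix. Each mix was made from 9 parts knockout and 1 part wild-type cells, both of the Ainv15 line, after 3 days in medium with LIF but without the inhibitors of MEK and GSK3 that hold such cells in the naive state. ZBTB11 and ZFP131 are transcription factors with a BTB domain and zinc fingers, and the series asks how they act on pluripotency and on RNA polymerase II pausing at differentiation genes. There are no replicates, and all intervals given are 95% intervals for counting error only.

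The first question was whether the knocked-out genes were lower in their own mixes. Zbtb11 (ENSMUSG00000022601, mm10 chromosome 16, 55973883 to 56008913, plus strand) had 13.6 CPM (12.7 to 14.4) in the Zbtb11-labelled mix and 19.9 (18.9 to 20.9) in the Zfp131-labelled mix, a log2 ratio of −0.55 (−0.67 to −0.44). Zfp131 (ENSMUSG00000094870, mm10 chromosome 13, 119765187 to 119790889, minus strand) had 28.3 CPM (27.1 to 29.5) in its own mix and 24.6 (23.4 to 25.7) in the Zbtb11-labelled mix, so it was not at a lower level in the mix labelled as its knockout. Neither gene passed the size rule. Tags at the 3' end can lie outside the deleted part, which is not given in the sources used here, and the wild-type cells add transcripts, so these levels check the genotypes only weakly. The genotype field of the second library names a Zbtb11 knockout, but its Zbtb11 level was not the lower of the pair.

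The comparison between the mixes asks how cultures made mostly of either knockout differed from one another. Some genes of naive pluripotency were higher in the Zbtb11-labelled mix. Nanog, a homeobox factor of the naive state, had 312 CPM (308 to 316) against 145 (142 to 148), a log2 ratio of 1.10 (1.07 to 1.14), and Klf2, another naive-state factor, had 48.6 against 20.3, a log2 ratio of 1.26 (1.17 to 1.35). Some formative and primed genes were higher in the Zfp131-labelled mix, where Otx2, a homeobox factor of the exit from the naive state, had 48.9 against 18.5, a log2 ratio of −1.40 (−1.49 to −1.32), and Pou3f1 had 19.6 against 6.33, a log2 ratio of −1.63 (−1.78 to −1.48). Among 8087 genes with at least 10 CPM in either mix, 241 were higher and 634 lower in the Zbtb11-labelled mix. The median log2 ratio of these genes was −0.24, and TMM scaling moved all ratios up by 0.14 and gave 314 higher and 453 lower genes.

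Pluripotency lists moved apart between the mixes. Of 13 naive genes, 3 were higher in the Zbtb11-labelled mix (Nanog, Klf2 and Prdm14), none was lower and 10 did not pass, with a list median of 0.45 at percentile 99.99 of matched random lists. Of 11 formative and primed genes, 3 were lower (Otx2, Pou3f1 and Lef1) and 8 did not pass, with a median of −1.07 at percentile 0.06. Only 5 of the 11 reached 10 CPM. Of 10 core genes, Utf1 was lower at −1.07 and 9 did not pass, with a median of −0.12 at percentile 62.5. Utf1 did not pass with TMM scaling, at −0.94. Pou5f1, the central factor of pluripotency, had 435 CPM against 777 and a log2 ratio of −0.84 (−0.85 to −0.82), and Sox2, its partner, −0.17. The Pou5f1 difference was also present in the shared cluster, at 447 CPM against 753 in the clustering without listed genes. It was thus not confined to the remaining cells. Zfp42, Klf4 and Esrrb had log2 ratios of 0.12, 0.57 and 0.32.

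A few genes of extraembryonic and embryonic lineages were lower in the Zbtb11-labelled mix. Of 15 primitive endoderm genes, the basement membrane genes Col4a1, Lama1 and Col4a2 were lower at −1.05, −1.04 and −1.03 and 12 did not pass, with a median of −0.75 at percentile 0.055. These 3 genes no longer passed with TMM scaling, with every cell weighted equally or without the primitive-endoderm-like, 2-cell-like and low-depth clusters, where Lama1 was at −0.10, Col4a2 at −0.62 and Col4a1 at −0.95. With TMM scaling and with equal weights all 3 lay under the rule, between −0.90 for Col4a2 and −0.99 for Lama1. Of 10 trophoblast genes, Ascl2 was lower at −1.08 and 9 did not pass, with a median of −0.71 at percentile 0.88, and Ascl2 was under the rule with TMM scaling, at −0.94. Of 9 neuroectoderm genes, 3 of them with at least 10 CPM, the proneural factor Neurod1 was lower at −2.67 (−2.76 to −2.57) and the Notch ligand Dll1 at −2.30, 7 did not pass, and the median was −0.57 at percentile 5.03. All 7 fibroblast genes stayed short of the rule, but only 1 of them reached 10 CPM, with a median of −0.90 at percentile 1.56. Few members of the next lists reached 10 CPM, 0, 3, 4 and 1 in turn. None of 11 streak and mesoderm genes passed (median −0.48, percentile 7.17), nor any of 7 definitive endoderm genes (median −0.27, mean 0.21, percentile 34.6), 10 neuron genes (median 0.04, mean −0.30, percentile 80.6) or 9 endothelium and blood genes (median 0.45, percentile 86.3). With members of at least 100 UMIs, the definitive endoderm and the endothelium and blood medians turned to 0.10 and −0.48.

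Hox genes, which set position along the body axis, leaned the other way. Of 35 measured, Hoxb1 was higher in the Zbtb11-labelled mix at 2.48 (2.24 to 2.74) and Hoxb2 at 2.31 (2.09 to 2.55), none was lower and 33 did not pass, with a list median of 1.18 at percentile 100. Only 4 of the 35 reached 10 CPM, so that median rests mostly on genes too low to pass the rule. Of 12 genes of the 2-cell-like state, Tmem92 was higher at 3.23 and Ddit4l lower at −1.05, with a median of 0.23 at percentile 94.4. Of 10 germ line genes, the meiotic gene Stra8 was higher at 1.08 and Taf7l lower at −1.26, with a median of 0.08 at percentile 89.0 that turned to −0.08 without the differentiated and low-depth clusters. Of 16 imprinted genes, Dlk1 was higher with 11.7 CPM against 4.14, Peg3 lower at −2.15 and Meg3 lower at −1.10, with a median of −0.26 at percentile 34.0. Ddit4l and Meg3 were under the rule with TMM scaling, at −0.92 and −0.97.

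Several targets of p53 and stress genes were lower in the Zbtb11-labelled mix. Of 14 p53 targets, the death receptor gene Fas (−1.98), Perp (−1.49), Ccng1 (−1.25) and the cell cycle inhibitor Cdkn1a (−1.10) were lower, and 10 did not pass, with a median of −0.66 at percentile 0.03. Cdkn1a was under the rule with TMM scaling, at −0.96, and without the differentiated and low-depth clusters, at −0.93. Of 17 genes of the integrated stress response, Cth (−1.32), Ddit3 (−1.22), Trib3 (−1.11) and Gdf15 (−1.09) were lower and 13 did not pass, with a median of −0.50 at percentile 2.22, and with TMM scaling Trib3 and Gdf15 were under the rule at −0.97 and −0.96. Of 10 immediate early genes, Junb (−1.25) and Fos (−1.24) were lower, with a median of −0.30 at percentile 27.1. For remaining over shared cells, the p53 target medians were 1.07 in the Zbtb11-labelled mix and 1.68 in the Zfp131-labelled mix. Those of the integrated stress response were −0.65 and 0.11, and the second turned to −0.03 with TMM scaling.

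Signalling lists moved in part. Of 13 ERK targets, Phlda1 (−1.16) and the phosphatase gene Dusp4 (−1.15) were lower and Spry4 was higher (1.10; 0.93 without the differentiated and low-depth clusters), with a median of −0.52 at percentile 3.73. Of 8 BMP targets, the helix-loop-helix genes Id2 (−2.06) and Id1 (−1.18) were lower, with a median of −0.44 at percentile 14.8. Of 7 Nodal pathway genes, the Nodal antagonist Lefty2 was higher at 1.44 (1.33 to 1.56), with a median of 0.31 at percentile 98.3. Of 9 Wnt targets, Lef1 was lower at −3.23, with a median of −0.09 at percentile 60.4, and of 9 LIF and STAT3 targets Junb was lower, with a median of 0.05, a mean of −0.07 and percentile 96.9. Of 16 genes of Pol II pausing and elongation, the elongation factor gene Ell2 (−1.51) and Larp7 (−1.16), which binds 7SK RNA, were lower and 14 did not pass, with a median of −0.20 at percentile 71.4.

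Genes of translation and metabolism included large single-gene differences. Of 82 cytosolic ribosomal protein genes, Rpl27a (1.29) and Rps4x (1.19) were higher in the Zbtb11-labelled mix and 80 did not pass, with a median of 0.38 at percentile 100. The same list had a median of 0.14 between the mixes within the shared cluster. For remaining over shared cells its median was −0.03 in the Zbtb11-labelled mix and −0.24 in the Zfp131-labelled mix. The shift from shared to remaining cells was thus larger in the Zfp131-labelled mix. Of 13 mitochondrially encoded genes, mt-Atp8 (1.34) and mt-Nd6 (1.08) were higher in the Zbtb11-labelled mix, with a median of 0.50 at percentile 99.8. The Zbtb11-labelled mix also had more cells in low-depth clusters, 17.1% against 7.54%, and the median mitochondrial share of those cells was 5.73% and 5.05%. Of 78 mitochondrial ribosome genes, 2 were higher, 9 were lower and 67 did not pass, with a median of −0.22 at percentile 54.5. The lower ones included Mrps31 (−2.79), Mrpl3 (−2.68) and Mrpl48 (−2.50). None of the 21 listed nuclear OXPHOS genes passed (median −0.05, mean 0.02, percentile 82.8). The complex I subunit gene Ndufc2 is outside that list. It had 13.1 CPM in remaining cells of the Zbtb11-labelled mix and 411 in those of the Zfp131-labelled mix. Of 13 glycolysis and hypoxia genes, Pdk1 (−1.16) and Pfkp (−1.01) were lower, with a median of −0.23 at percentile 32.2, and Pfkp was under the rule with TMM scaling, at −0.88, and with the stricter cell filter, at −0.997. None passed among 13 cholesterol synthesis genes (median 0.17, percentile 99.8), 18 S phase genes (median −0.26, percentile 34.9), 18 G2 and M phase genes (median 0.03, mean −0.07, percentile 97.6) or 10 interferon response genes (median 0.18, percentile 74.8). With members of at least 100 UMIs the interferon median turned to −0.29. With TMM scaling the medians of the core, Wnt and OXPHOS lists turned to 0.01, 0.05 and 0.09, and the Wnt median was 0.18 with members of at least 1 UMI.

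Some of the largest differences were in genes outside the lists, although Lef1, among the lowest below, is a listed gene. Rmdn3, a mitochondrial tethering protein gene, had 48.3 CPM in the Zbtb11-labelled mix and 5.58 in the Zfp131-labelled mix, a log2 ratio of 3.12 (2.97 to 3.26). Magohb (2.96), Tbl3 (2.63), Noc4l (2.43) and the RNA exosome subunit gene Exosc7 (2.36) were higher in the same mix. Also among the 12 highest were Pdgfrl, Arg2, Mecr, Platr31, Gpr89, Med9 and Lrrc14, between 2.98 for Pdgfrl and 2.46 for Lrrc14. The lowest were the Y-linked Eif2s3y (−4.62, −4.99 to −4.26), followed by Glipr1 (−4.29) and Creb5 (−4.20). Csn3, Ddx3y, Sct, Ms4a10, Tbc1d19, Aass, Lef1, Pex3 and Zdhhc6 completed the 12 lowest, from −4.19 for Csn3 to −2.99 for Zdhhc6. Reads of genes with near-identical copies, such as Rps4x, may be shared among the copies.

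Clustering of all cells gave 11 clusters, and the question was which cell states each mix held. A naive-like cluster, with higher Klf2, Tfcp2l1, Esrrb, Prdm14, Fgf4 and Tcl1 than other cells, held 9.76% (9.08 to 10.5) of the Zbtb11-labelled mix and 7.80% (7.18 to 8.46) of the Zfp131-labelled mix, or 699 and 539 cells. It was the only large cluster with a sizeable share of both and is called the shared cluster. At resolution 1.0 another naive-like cluster, with higher Klf4, Prdm14 and Nanog, held 37.7% of the Zbtb11-labelled mix and 0.130% of the other. Primitive-endoderm-like cells, with all 15 markers higher, formed 9.45% (8.78 to 10.2) and 9.23% (8.56 to 9.94), in cluster 7 for the Zbtb11-labelled mix and cluster 8 for the Zfp131-labelled mix. The 2-cell-like cluster 6 held 11.6% (10.9 to 12.3) and 1.27% (1.02 to 1.57), but after thinning to 5000 UMIs Zscan4a, a gene of the 2-cell embryo, was seen in 15.7% of its cells from the Zbtb11-labelled mix and in 45.1% of those from the other. In the 2-cell-like cluster made without listed genes, Zscan4c was at 125 CPM in cells of the Zbtb11-labelled mix and 1307 in those of the other. With all listed genes left out of the clustering, the primitive-endoderm-like shares were 8.56% and 9.18%, the 2-cell-like shares 12.0045% and 1.33% and the shared cluster 9.76% and 7.80%, and a primed-like cluster with higher Otx2, Pou3f1, Sall2, Cdh2 and Lef1 held 42.8% of the Zfp131-labelled mix and 0.0419% of the other. With the listed genes included no cluster was primed-like at the chosen resolution, and 49.9% of those cells of the Zfp131-labelled mix fell in cluster 3, which had 9 of 10 trophoblast markers higher but was left unnamed because another class led its top genes. At resolution 1.0 a trophoblast-like cluster held 7.19% of that mix. The primed-like share depends on the resolution, since with listed genes included a primed-like cluster held 78.4% of the Zfp131-labelled mix at resolution 0.3 and 15.4% at 1.0.

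**Figure D1:**
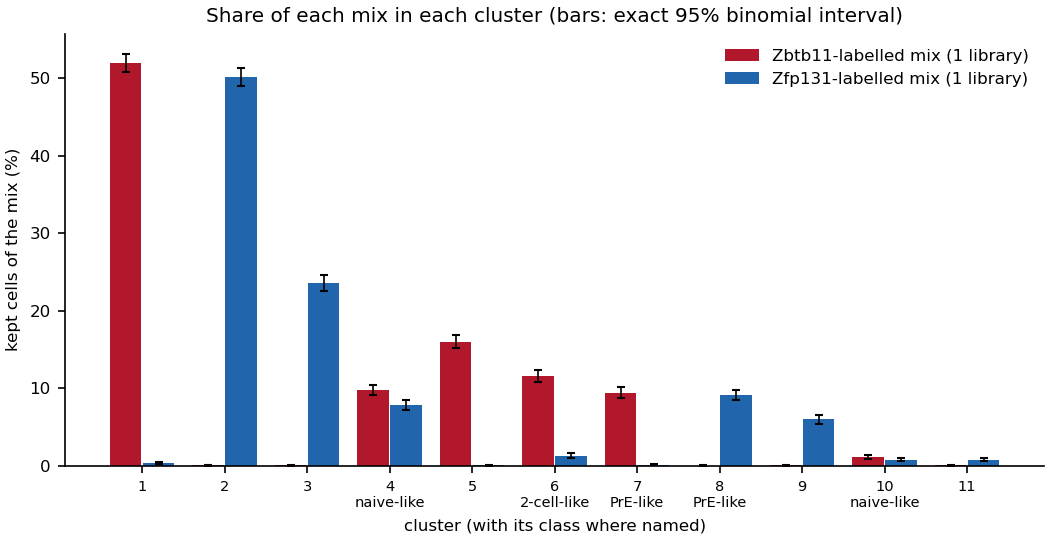
Share of each mix's cells (percent) in each of 11 clusters, with bars for the mixes and lines for exact binomial 95% intervals. Cluster 4 held 9.76% and 7.80% of the mixes, while cluster 1 held 52.0% of one and 0.362% of the other.

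Of the 11 clusters, 7 held at least 95% cells of 1 mix and together 83.4% of cells, so that a cluster of this kind may stand for a library as much as for a cell state. Clusters 1 and 5 held 52.0% and 16.0% of the Zbtb11-labelled mix, and clusters 2 and 3 held 50.2% and 23.6% of the Zfp131-labelled mix. Clusters 5, 9, 10 and 11 had low depth, with median UMIs of 5041 and 4462 in the mixes, and held 17.1% and 7.54% of cells.

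After thinning to 5000 UMIs, Otx2 was seen in 8.01% of cells of the Zbtb11-labelled mix and 18.7% of the Zfp131-labelled mix, against 0.648% and 1.15% of primitive-endoderm-like cells. Klf2 was seen in 18.8% and 7.42% of cells, against 6.32% and 1.65% of primitive-endoderm-like cells. These shares depend on depth. With thinning to 3000 UMIs Otx2 was seen in 5.22% and 11.8% of cells of the mixes and Klf2 in 11.5% and 4.41%. Without thinning the shares were 14.0% and 28.5% for Otx2 and 31.8% and 13.4% for Klf2. Gata6, a primitive endoderm factor, was seen in 10.2% of cells of the Zfp131-labelled mix, against 0.564% in its shared cluster, and Zscan4a in 2.83% and 0.926% of cells of the mixes, against 1.01% and 0.188% in the shared cluster.

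**Figure D2:**
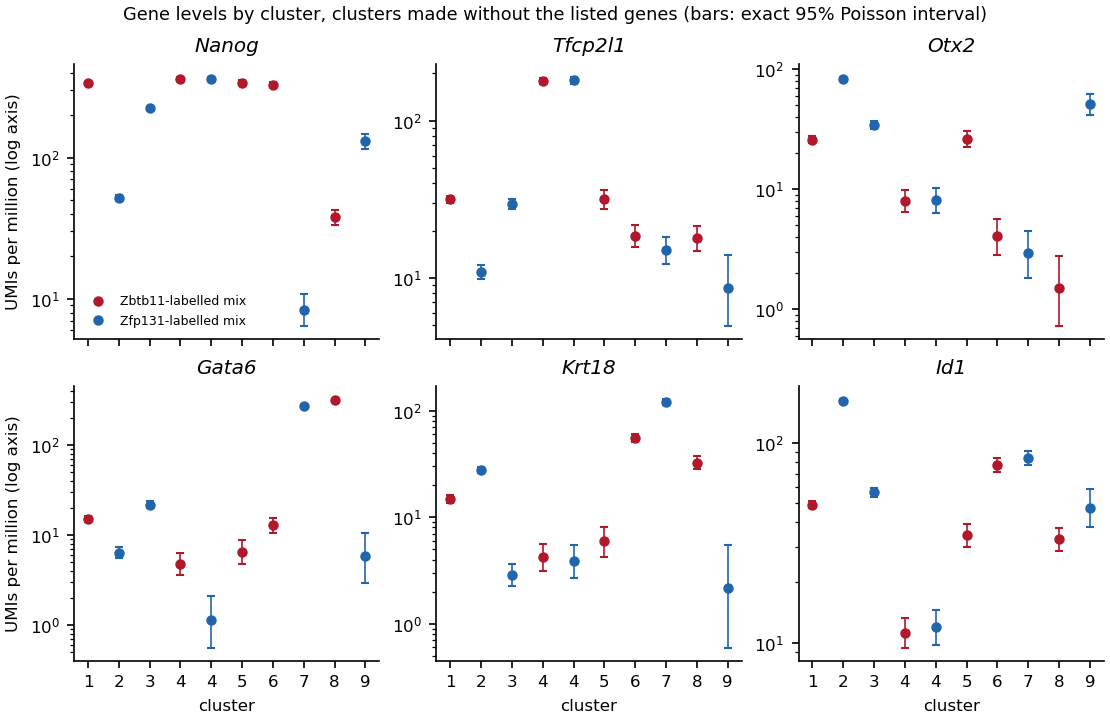
CPM (log axis) of Nanog, Tfcp2l1, Otx2, Gata6, Krt18 and Id1 in each cluster of the clustering made without listed genes, for clusters with at least 300 cells of a mix, with Poisson 95% intervals. Nanog stood at 51.6 in the primed-like cluster of the Zfp131-labelled mix and at 363 and 360 in the shared cluster.

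The remaining cells of each mix were then compared with the shared cluster of the same mix, a comparison of clusters that carries no genotype. The remaining cells were shallower, with medians of 9518 UMIs against 15752 in the Zbtb11-labelled mix and 10027.5 against 15949 in the Zfp131-labelled mix, and their median mitochondrial share was 2.87% against 1.63% and 2.20% against 1.68%. In the Zbtb11-labelled mix, the naive factor gene Tfcp2l1 had 29.2 CPM in remaining cells against 178 in the shared cluster, a log2 ratio of −2.61 (−2.70 to −2.52), and in the Zfp131-labelled mix 18.6 against 182, a log2 ratio of −3.29. Nanog was lower in the remaining cells of the Zfp131-labelled mix, 117 against 360 at −1.62 (−1.68 to −1.56), and had −0.26 in the other. The p53 target Mdm2, which encodes the ligase that degrades p53, was higher in remaining cells of both mixes at 1.95 (1.86 to 2.04) and 2.61. Of 7901 genes in the Zbtb11-labelled mix, 677 were higher and 553 lower in remaining cells, and of 8313 in the Zfp131-labelled mix 1241 were higher and 576 lower. The medians of all genes were 0.02 and 0.18. TMM scaling moved all ratios down by 0.10 and 0.14. It gave 598 higher and 687 lower genes in the first mix, where the majority turned, and 947 and 732 in the second.

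Many of these genes passed in both mixes. Among 7645 genes measured in both, 444 were higher in both and 271 lower in both. TMM scaling gave 369 and 349. The comparisons in both mixes refer to the same naive-like cluster, so that overlap is partly built in and was not tested. The log2 ratios had a Pearson correlation of 0.746 and a Spearman correlation of 0.723 across genes, which are not independent replicates. Cul9 was higher in the Zbtb11-labelled and lower in the Zfp131-labelled mix, and Aass, Ddx1, Platr17, Sar1b and Zmpste24 went the opposite way.

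**Figure D3:**
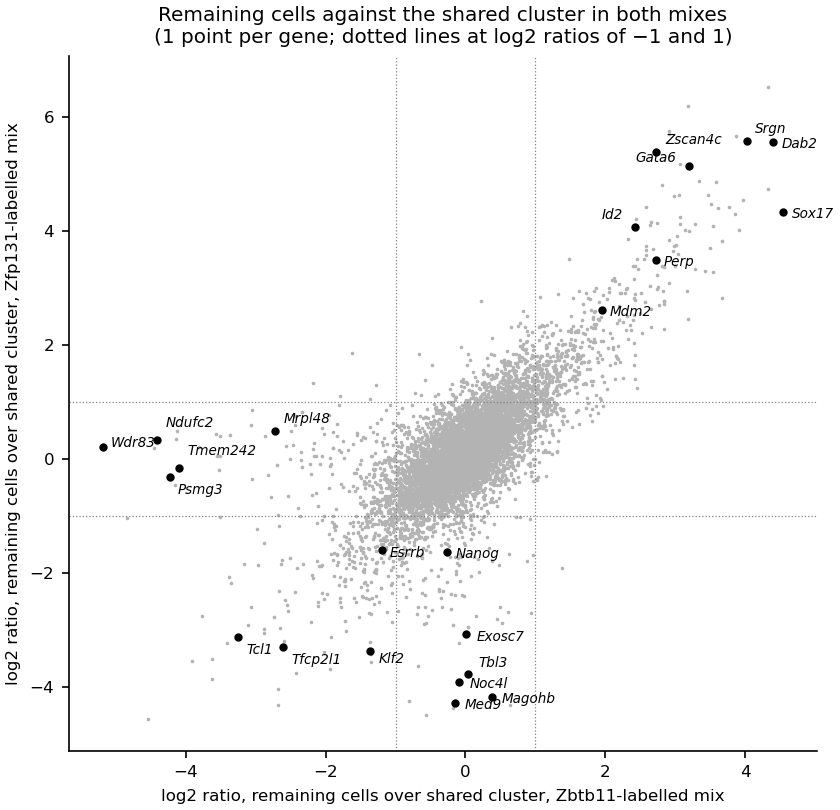
Log2 ratio of remaining cells over the shared cluster for each gene, in the Zbtb11-labelled mix (horizontal) and the Zfp131-labelled mix (vertical). The Pearson correlation across genes was 0.746.

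Of 13 naive genes, 5 were lower in the remaining cells of the Zbtb11-labelled mix and 8 did not pass (median −0.44, percentile 0.32), and 7 were lower in the Zfp131-labelled mix and 6 did not pass (median −1.60). The lower ones included Tcl1 (−3.25 and −3.12), Klf2 (−1.36 and −3.36) and Esrrb (−1.20 and −1.60). Pou5f1 had −0.04 and 0.04. Of 11 formative and primed genes, 1 rose in the Zbtb11-labelled mix (Otx2, 1.33) and 4 in the other (Pou3f1 3.66, Lef1 3.44, Otx2 2.90 and the DNA methyltransferase gene Dnmt3a 1.30), and both medians were 1.30 at percentile 99.2. Only 3 and 5 of the 11 reached 10 CPM, so these medians rest mostly on genes too low to pass the rule. Their equality does not show an equal shift in both mixes. Of 15 primitive endoderm genes 13 were higher in each mix, with medians of 3.07 and 4.34, and of −0.04 and 0.78 without the primitive-endoderm-like and 2-cell-like clusters.

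Of 14 targets of p53, 6 were higher in remaining cells of the Zbtb11-labelled mix and 12 in the Zfp131-labelled mix and the others did not pass, with medians of 1.07 and 1.68 at percentile 100. Perp was at 2.72 and 3.49 and Fas at 4.84 in the second mix. Of 8 BMP targets 3 were higher in each mix, among them Id1 (2.13 and 3.18) and Id2 (2.43 and 4.06). Of 13 ERK targets 5 and 6 were higher, and 1 was lower in the Zbtb11-labelled mix, with Phlda1 at 3.01 and 3.75 and Dusp6 at 2.06 and 2.99. The lower one, Egr1 (−1.06), was under the rule at −0.91 without the primitive-endoderm-like and 2-cell-like clusters. None of the 16 genes of Pol II pausing and elongation passed in either mix, with medians of −0.21 and 0.05, the second turning to −0.10 with TMM scaling.

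Some genes of metabolism and growth were lower in remaining cells. Of 13 glycolysis and hypoxia genes 5 and 4 were lower and 1 was higher in the Zbtb11-labelled mix, the lower ones including the lactate dehydrogenase gene Ldha (−1.84 and −1.66), and of 13 cholesterol synthesis genes 3 and 5 were lower. Of 18 S phase genes 3 and 2 were lower, including Uhrf1 (−1.63 and −1.53), which maintains DNA methylation. Ung, at −1.09 in the Zbtb11-labelled mix, was under the rule at −0.94 without the primitive-endoderm-like and 2-cell-like clusters. Of 16 imprinted genes 6 and 9 were higher and 1 lower in each mix, with H19 at 3.61 and 4.39.

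Other genes were lower in the remaining cells of 1 mix and within 0.5 of 0 in the other, a choice made after the values were seen, and the difference between the mixes was not tested. In the Zbtb11-labelled mix there were 148 such genes, and 55 that were higher by the same choice. Ndufc2, a complex I subunit gene, had 13.1 CPM against 277, a log2 ratio of −4.41 (−4.52 to −4.30), where the other mix had 411 against 325 and 0.34. Ndufaf1 (−3.80), a complex I assembly factor gene, Wdr83 (−5.19), Psmg3 (−4.23) and Tmem242 (−4.10) were also lower there. In the Zfp131-labelled mix there were 115 lower genes and 258 higher ones. Noc4l had 4.26 against 64.0, a log2 ratio of −3.91 (−4.12 to −3.70), and −0.09 in the other mix, and Tbl3 (−3.76), Magohb (−4.17), Exosc7 (−3.07) and Rrp1 (−2.75) were lower as well. Noc4l, Tbl3 and Rrp1 act in ribosome production and Magohb in the exon junction complex.

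**Figure D4:**
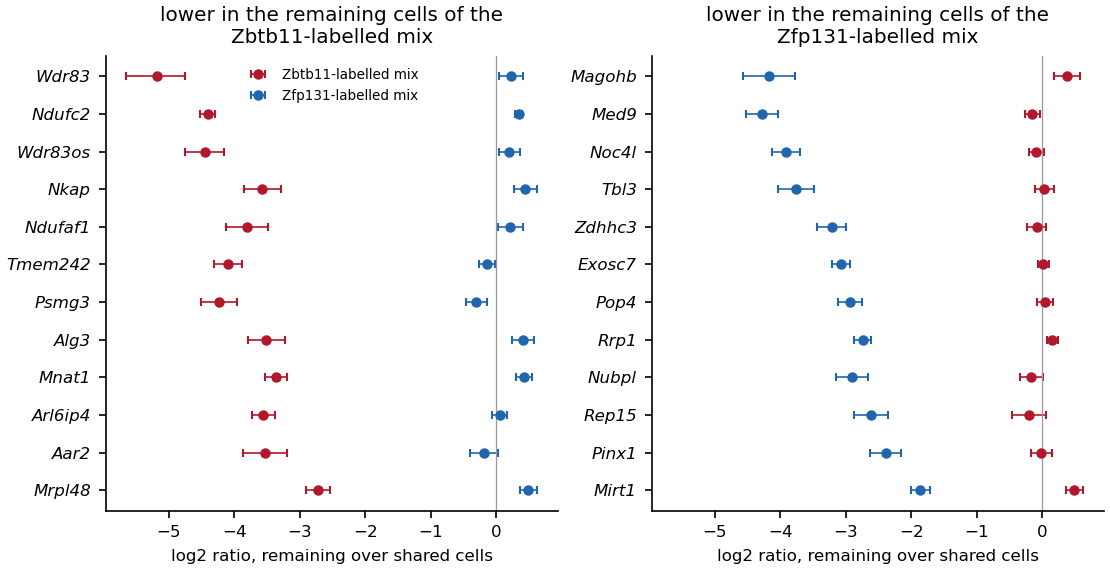
Log2 ratio of remaining cells over the shared cluster, with 95% intervals for counting error, for 12 genes lower in 1 mix on each side. Ndufc2 stood at −4.41 in the Zbtb11-labelled mix and 0.34 in the Zfp131-labelled mix.

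Within the shared cluster few genes passed between the mixes, but some list medians were high or low. The 2-cell-like median was 1.68 (6 measured genes, percentile 99.99) and the primitive endoderm median 0.34 (percentile 99.8). Cytosolic ribosomal proteins had a median of 0.14 (percentile 100) and the integrated stress response −0.18 (percentile 1.6). No member of these lists passed. Of the measured 2-cell-like and primitive endoderm genes, however, only 1 of 6 and 2 of 14 reached 10 CPM. Most of them could therefore not pass, and those 2 medians rest on low levels. Of 7407 genes, 21 were higher and 7 lower in the Zbtb11-labelled mix, against 315 and 808 of 8145 genes between the remaining cells. The higher genes included Platr31 (2.80), the nucleotide kinase gene Nme2 (1.83, 1.71 to 1.96) and Dynlt1b (1.81), and the lower ones the nuclear RNA Neat1 (−1.02). Nanog had 364 and 360 CPM, a log2 ratio of 0.02 (−0.05 to 0.08), and Pou5f1 447 and 758, a log2 ratio of −0.76 (−0.82 to −0.71). Zbtb11 had a log2 ratio of −0.05 (−0.35 to 0.25) in the shared cluster, whereas within the Zbtb11-labelled mix it had 12.7 CPM in remaining cells against 18.6, a log2 ratio of −0.56 (−0.78 to −0.33). Zfp131 had 28.3 in remaining and 28.2 in shared cells of its own mix.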

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

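The settings without highest doublet scores, without listed genes, with thinned cells, and without differentiated or low-depth clusters were chosen after the data were examined, as was every comparison of remaining cells with the shared cluster. Of 4656 values under other settings 48 changed sign: 9 list medians between the mixes, 17 of remaining over shared cells, 20 ratios of named genes and 2 differences in marker shares. Of these, 2 were lists called high or low. Of 3033 calls of named genes 48 ended. With at least 1 CPM the higher and lower genes in the Zbtb11-labelled mix numbered 864 and 1460, and with at least 50 they numbered 78 and 213, by construction of the limit. The same limits gave, for remaining against shared cells, 2403 and 1046 or 141 and 193 in the Zbtb11-labelled mix and 3155 and 1231 or 386 and 197 in the Zfp131-labelled mix, for genes in both mixes 1514 and 530 or 90 and 92, and within the shared cluster 255 and 270 or 9 and 0. TMM scaling gave 30 higher and 4 lower genes within the shared cluster, Zbtb11 at −0.42 and Zfp131 at −0.0697 between the mixes, and list medians of −0.53 for p53 targets, −0.37 for the integrated stress response, 0.52 for cytosolic ribosomal proteins and 0.16 for G2 and M phase. Without the differentiated and low-depth clusters the primitive endoderm median between the mixes was −0.31 and the G2 and M phase median turned to −0.0097, with the cause not tested. Without the primitive-endoderm-like and 2-cell-like clusters the primitive endoderm median of remaining over shared cells in the Zbtb11-labelled mix turned to −0.0352, since the cells with those genes were left out.

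The primitive-endoderm-like share of the Zbtb11-labelled mix was 8.56% without listed genes, 8.67% with doublet calls kept and 8.26% without the highest doublet scores. In the Zfp131-labelled mix it was 10.5% at resolution 0.3, 10.8% at 1.0, 10.6% with 20 components, 10.8% with 3000 variable genes, 10.7% without a cell filter, 10.9% with doublet calls kept, 10.7% without the highest doublet scores and 11.2% with thinned cells. The 2-cell-like share of the Zbtb11-labelled mix was 12.5% without a cell filter, 10.5% without the highest doublet scores and 9.73% with thinned cells. The shared cluster held 11.2% and 8.46% of thinned cells. The cause of these shifts was not tested. Settings with another minimum of GFP UMIs could not be run, since H2B-GFP had 0 UMIs. The minimum of 10 CPM in the size rule was a chosen limit, and genes under it in both arms are left out.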

Other observations

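The test of a library effect on every cell and that of wild-type cells were set before their results were seen, and the tests of depth, deep cells, doublets of remaining cells, knockout cells that stayed naive and both tests of low Y-linked levels were chosen only afterwards. The test of doublets replaced 2 earlier ones, of which the removal of high doublet scores was void because the caller did not work, and the range over all clusters of at least 50 cells left doublets open, so its limit on the size of parent clusters was chosen with those results known. Of 9 measured trophoblast genes, 2 (Krt8 and Krt18) were higher in the remaining cells than in the shared cluster of the Zbtb11-labelled mix and 4 in the Zfp131-labelled mix, and 7 and 5 did not pass, with medians of 1.59 and 1.95. Ascl2, at 1.08 in the Zfp131-labelled mix, was under the rule with TMM scaling, at 0.94. Of the measured 2-cell-like genes 5 of 12 and 4 of 10 were higher, with medians of 2.93 and 2.45, or 1.01 and 1.23 without the primitive-endoderm-like and 2-cell-like clusters. Of the measured Hox genes 4 of 35 and 2 of 30 were higher, which were all those with at least 10 CPM, with Hoxb1 at 4.69 in the Zbtb11-labelled mix. Hoxc13, at 1.09 in the Zfp131-labelled mix, was under the rule in some settings. It was at 0.96 without the primitive-endoderm-like and 2-cell-like clusters, 0.97 with every cell weighted equally and 0.95 with TMM scaling. In the Zbtb11-labelled mix 10 of 78 mitochondrial ribosome genes were lower in remaining cells, among them Mrpl48 (−2.72) and Mrpl30 (−2.20), and in the Zfp131-labelled mix 6 were lower, among them Mrpl55 (−2.60) and Mrpl4 (−1.97).

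Apart from the shared cluster and the 2-cell-like cluster, of which 90.4% came from the Zbtb11-labelled mix, the large clusters held almost only cells of 1 mix. An effect of library preparation on every cell would part the shared cluster too, but 28 genes passed there between the mixes, against 1123 between the remaining cells. That cluster was chosen for holding both mixes, so part of this is built in, although each ratio used cells grouped by other genes. Effects on single genes or lists are not excluded. Pou5f1 had −0.76 there and −0.84 between the whole mixes, and the cytosolic ribosomal protein median was 0.14 there and 0.38 between the whole mixes. Depth is argued against as well, since after thinning all cells to 5000 UMIs 84.3% of cells still lay in clusters of at least 95% from 1 mix. A technical effect on a part of the cells was not tested, and with 1 library per mix the difference between the knockouts or their clones stays open beside it.

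The shared cluster stood apart from the remaining cells of both mixes, and deep cells are argued against as the source, because 99.1% of its cells of sufficient depth returned to it after thinning. Knockout cells that only stayed naive would carry the Y-linked level of the remaining cells, but in a clustering without Y-linked genes the log2 ratio of remaining over shared cells was −3.84 (−4.33 to −3.37) in the Zbtb11-labelled mix and 1.87 (1.61 to 2.14) in the Zfp131-labelled mix, which leaves open a group of knockout cells with another Y content. Doublets of remaining cells would lie within the range of clusters large enough to be their parents, but the shared Y-linked level lay outside it by 1.70 (1.06 to 2.39) and −1.62 (−1.93 to −1.32) on the log2 scale. Of genes past the rule 78.1% and 68.5% also lay outside that range, or 13.2% and 4.07% with smaller clusters, among them a naive-like one, counted as parents. Those genes were chosen for differing between shared and remaining cells, which favours lying outside, so these shares add no support. Wild-type cells, at 1 part in 10 of each pool, are a candidate explanation that stays open. The median difference of 0.22 between the mixes in shared cells met the limit set beforehand for wild-type cells. It does not tell them from other cells alike in both, and nor do the similar Y-linked levels of shared cells, 12.1 and 14.3 CPM. Of the targets, Zbtb11 was at −0.56 (−0.78 to −0.33) in remaining over shared cells of its mix and Zfp131 at 0.01 in its own. These target levels are a weak check, because 3' tags can lie outside the deleted part.

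Y-linked transcripts of Ddx3y, Eif2s3y, Uty and Kdm5d, chosen after their values were seen, summed to 2.46 CPM (2.12 to 2.84) in the Zbtb11-labelled mix and 47.9 (46.4 to 49.5) in the Zfp131-labelled mix. A lower level in all cells of the mix is argued against by the shared cluster, where the log2 ratio was −0.24 (−0.60 to 0.12). The difference between the mixes lay −4.05 from the median of all genes, which scaling would move alike. Because the genes were chosen after their values were seen, this test of scaling could hardly come out otherwise and adds no support. The levels were 12.1 and 14.3 CPM in shared cells and 0.762 and 52.4 in remaining cells. Loss of the Y chromosome in the line behind the remaining cells of the Zbtb11-labelled mix may account for their low level, but not for the lower level of shared than remaining cells in the Zfp131-labelled mix, and it was not tested.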
